A study of Danio rerio with 16 samples.

How the data were processed

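Whole zebrafish eleuthero-embryos, the stage that has hatched but still draws on its yolk, were profiled at 6 days post fertilisation on Agilent 4 x 44K zebrafish oligonucleotide arrays. Per the labels' protocols, eggs were exposed from the blastula stage in covered 750 mL glass beakers to water alone, to 0.01% DMSO as solvent control, or to nominal concentrations of 2 or 40 µg/L PKC412. PKC412 is midostaurin, a staurosporine derivative that inhibits several kinases, among them protein kinase C, FLT3, KIT and the VEGF receptors. Each of 6 exposure replicates per group held 100 eggs, and 80 embryos per replicate were pooled for RNA. Arrays exist for 4 pools per group, 16 in all, so each replicate is a pool from its own beaker. Labelling started from 600 ng of total RNA with 1 dye (Cy3). The labels do not say whether the PKC412 beakers also held DMSO. The treatment and source labels of the 40 µg/L samples name PKC412, whereas their descriptions name PKC413 to PKC416, 1 for each sample, and the treatment label was followed. The series text gives a total of 12 arrays but lists 4 for each of the 4 groups, and all 16 were used. Numbers attached to some deposited arrays differ from the replicate numbers in the labels, which are the ones used here.

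The deposited scanner files hold, per the file headers, spot intensity on a linear scale from Agilent Feature Extraction 10.5.1.1, run with background subtraction and detrending within each array. The processed signal of each spot was used. The deposited series table held the same intensity values: 0 of 45220 spots per array differed from the scanner files. Any further normalisation by the authors is not given in the sources used here. The number of arrays limits the precision, since arrays give no counts.

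From these values, 1417 control spots per array were left out, spots flagged as non-uniform or as population outliers were set to missing, and spots of the same probe were averaged (50 probes were spotted more than once). The processed signal was put on the log2 scale and the 75th percentile of each array was subtracted. A probe was tested where it was well above background, by the scanner software's own call, on every array of at least 1 of the 4 groups. This kept 30798 of 43603 probes. Outlying spots left some tested probes without a value on 1 or more arrays, so the principal components rest on 30623 probes. Gene symbols came from matching the array's RefSeq accessions, without versions, to a name table of 49597 zebrafish genes. Of 16036 probes with a curated accession 14767 matched, and of 2989 with a predicted accession 391 matched. In all 15163 probes carried a symbol, for 10536 symbols, and 28440 did not and are unnamed here. No genome sequence was used, and no coordinates are given.

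Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with tables read by the data.table package (version 1.17.8). All 16 arrays entered 1 fit of the 4 groups, so that the comparisons share 1 estimate of the spread. Errors on log2 changes are standard errors from that fit, with n = 4 pools per group. Tests are two-sided, p-values were adjusted over all tested probes by the Benjamini-Hochberg method, and an adjusted p under 0.05 is called changed. The comparisons were 40 µg/L against DMSO, 2 µg/L against DMSO, 40 against 2 µg/L, and DMSO against water. A fold change of a named gene is that of 1 probe, and the text says where probes of a gene disagree.

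Gene lists were tested with camera from limma at its preset inter-gene correlation of 0.01, on the brightest probe of each of 9794 genes, with Benjamini-Hochberg adjustment over the 31 lists. A list's median is that of its members' log2 changes. The lists cover kinases of the families PKC412 inhibits, together with atypical protein kinase C, vascular endothelium and angiogenesis, erythroid cells and haem synthesis, myeloid cells, inflammation and acute phase, the p53 response and apoptosis, cell cycle and DNA replication, and DNA repair. They also cover oxidative stress and glutathione, AhR and xenobiotic metabolism, heat shock and ER stress, the circadian clock, skeletal muscle, cardiac muscle, exocrine pancreas, liver and plasma proteins, vitellogenin and oestrogen response, intestinal epithelium, photoreceptors and phototransduction, lens crystallins, and neurons and glia. The rest are melanophores, xanthophores and iridophores, cholesterol synthesis, fatty acid metabolism, cartilage, bone and matrix, keratins and skin, immediate early genes, glucocorticoid response and gluconeogenesis, the thyroid axis, and glycolysis and hypoxia. The RNA is from whole bodies, so every list's tissue is part of the sample. Some genes sit in more than 1 list. Camera was repeated with a correlation estimated from each list, and fry tested whether a list's genes moved, on balance, one way, without comparing them with other genes. A member's call comes from the adjustment over all tested probes, and a second count, adjusted over the list alone, stands beside it.

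Genes were named by a fixed rule. Part (a) took, in each direction, the 10 probes with the largest change among those that passed the test, whose 4 arrays of one group all lay on one side of the other group's 4, and that carried an informative symbol, 1 probe per gene. Part (b) took from each list up to 4 members with the smallest adjusted p. Part (c), for comparisons with fewer than 10 changed probes, was not needed. For length, genes of (a) whose probe was not well above background on all 8 arrays compared were left out, except asb15b and pmelb. From (b) the text names mostly the first 1 or 2 genes of the lists that were called, and fewer from the others. This shortening was made after the values were seen, and it favours steady calls. Counting a gene once per comparison and part of the rule, leaving out 1 array ended the call at least once for 37 of the 127 called entries named here, and for 89 of the 128 not named. The design, tests, lists, naming rule and most of the alternatives were set before the data were examined.

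The 4 arrays of each group share 1 slide and 1 scan, and no slide holds more than 1 group. Slide, scan and group cannot be told apart, and no fit with the slide as a term could be had. This applies to every comparison between groups. The exposure, RNA preparation and labelling batches are not given.

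The fit was tested on simulated data with the real probes' levels and spreads, 30623 probes and 200 changed ones. For 40 µg/L against DMSO it recovered 63% of changes of 1 log2 unit and 89% of those of 2, with 8 false calls. For 2 µg/L against DMSO the shares were 51% and 88%, with 8 false calls, and for 40 against 2 µg/L 55% and 91%, with 7. For DMSO against water they were 49% and 89%, with 16 false calls. All 4 groups were simulated with the same spread per probe, pooled over the groups, so these figures differ only by the random draw. Real 40 µg/L arrays lay on average 0.595 to 0.873 (root mean square log2 difference) from their own group, and 2 µg/L arrays 0.341 to 0.388. The simulation thus could not show recovery or false calls under such unequal spread. In the list test, simulated for 40 µg/L against DMSO with 1 shifted list over 9762 genes, 1 of 31 lists was called, the shifted one. Simulated probes and genes varied independently of each other. The list simulation therefore could not show how camera does where genes of a list vary together, as in the real data. There the estimated correlation was, for example, 0.68 for liver and plasma proteins.

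Alternatives were quantile normalisation, median centring, normexp background correction with an offset of 50, other filters on dim probes, and outlying spots kept. Further ones were the replicate number as a block, only the 8 arrays compared, array weights, a trended and robust variance prior, the water group or both control groups as control, other thresholds, an ordinary test per probe, and each array left out in turn. The normexp correction took the median signal of each spot in place of the mean signal, which was not used here. That substitution, a normexp fit with its background taken from the negative control spots, leaving out 40 µg/L replicate 2 from comparisons without that group, and the split of calls by annotation under other scalings were chosen after seeing the data. Per-array means of lists and of clock genes were compared by exact permutation of 4 against 4 arrays, where the smallest possible two-sided p is 0.0286. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.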

Results

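The data comprised 16 one-colour arrays of whole zebrafish eleuthero-embryos at 6 days post fertilisation. Water controls, 0.01% DMSO controls, 2 µg/L PKC412 and 40 µg/L PKC412 had 4 arrays each, and every array carried RNA from 1 pool of 80 embryos. The 75th percentile of the processed signal ranged from 470 to 1223 intensity units, and 49.4% to 79.2% of probes on an array were well above background. Saturated spots numbered 0. The SD of the negative control spots was 4.06 to 16.0 intensity units on the water arrays and 1.70 to 2.64 on the others. Arrays of the same group correlated at 0.956 to 0.994 across probes, which are not independent replicates. The first 3 principal components held 40.4%, 15% and 11.7% of the variance. On the first, the 2 µg/L arrays lay between -66.8 and -43.9, whereas the 40 µg/L arrays lay at -34.2, 122.5, 47.9 and 56.3. The 40 µg/L pools thus differed more from each other than those of any other group did on this axis. Group and slide cannot be told apart in any comparison, since each group was hybridised on a slide of its own.

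**Figure D1:**
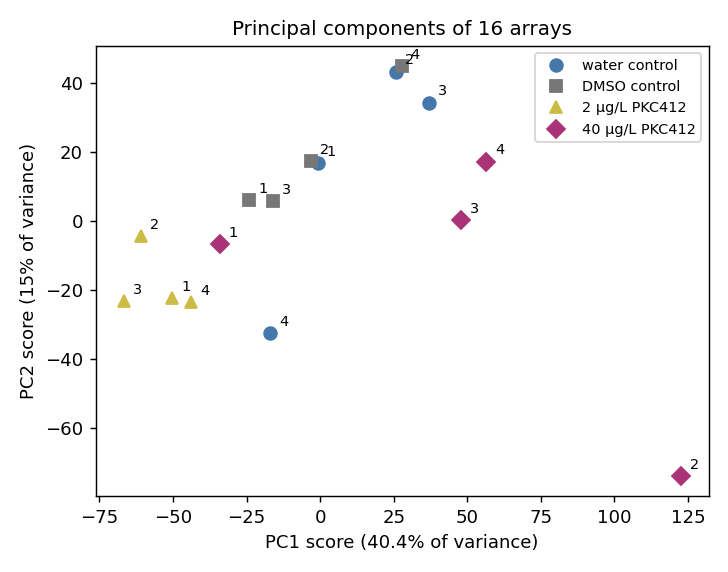
Scores of the 16 arrays on the first 2 principal components of the normalised log2 signal (unitless axes, with the share of variance, 40.4% and 15%). Each point is 1 array coloured by group, and the 40 µg/L arrays spread from -34.2 to 122.5 on the first component.

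At 40 µg/L PKC412, 7 of 19 intestinal genes fell against DMSO controls (camera adjusted p = 1.75e-12 for the list, and adjusted p = 0.622 with an estimated correlation). Single clock and photoreceptor genes differed in both directions. The clock repressor nr1d1, a Rev-erb nuclear receptor gene, was 7.4-fold lower (log2 change -2.89 ± 0.43 (SE), n = 4 pools per group, adjusted p = 0.00284), and its second probe gave -3.48. The apolipoprotein gene apoa4a was 7.5-fold lower (-2.91 ± 0.43, adjusted p = 0.00302), and eevs, which makes the sunscreen compound gadusol, was 6.93-fold lower (-2.79 ± 0.39, adjusted p = 0.00212). The hypoxia-responsive gene ndrg1b was 4.26-fold higher (2.09 ± 0.31, adjusted p = 0.00319), and bmal1a, whose product pairs with Clock, was 3.12-fold higher (1.64 ± 0.32, adjusted p = 0.0106). Each of these calls held with every array of the comparison left out in turn and with water in place of DMSO as the control. By an ordinary test per probe, which uses only the probe's own 8 arrays, 0 of the 41 gene calls named for this comparison held. With only the 8 arrays compared in the fit, 22 of the 41 held.

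Of 27 circadian clock genes measured, 6 rose and 7 fell at 40 µg/L (10 and 10 adjusted over the list alone). Their median change was 0.11 and their mean -0.06, and the list as a whole was not called by camera, which gave it a downward direction (adjusted p = 0.332). The period repressor per1b was 3.17-fold lower (-1.66 ± 0.22, n = 4, adjusted p = 0.0013). The photolyase gene cry5 was 2.86-fold lower (-1.51 ± 0.23, adjusted p = 0.00341) and the clock output factor tefa was 2.11-fold lower (-1.08 ± 0.16, adjusted p = 0.00337). Without 40 µg/L replicate 1, 10 clock genes were higher, and without 40 µg/L replicates 3 and 4 or DMSO replicates 1, 2 and 4 the number was 3, 2, 2, 2 and 4. Those lower stayed between 6 and 9. Among 41 photoreceptor genes 7 rose and 8 fell (11 and 12 adjusted over the list alone; camera adjusted p = 0.778). The cone arrestin gene arr3b was 3.49-fold lower (-1.80 ± 0.25, adjusted p = 0.00215) and the cone phosphodiesterase gene pde6c 1.75-fold lower (-0.81 ± 0.13, adjusted p = 0.00405). The blue opsin gene opn1sw2 was 2.15-fold higher (1.11 ± 0.19, adjusted p = 0.00609). Photoreceptor genes higher numbered 12 without 40 µg/L replicate 1, and 3 without 40 µg/L replicate 4 or DMSO replicate 1 or 2. Photoreceptor genes lower numbered 4 without DMSO replicate 1.

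Intestinal epithelium genes were lower at 40 µg/L than in DMSO, with 7 of 19 measured members down and 0 up (16 down adjusted over the list alone). Their median log2 change was -0.79, with an adjusted p of 1.75e-12 by camera (adjusted p = 0.622 with an estimated correlation). The meprin gene mep1a.1, a brush border protease, was 2.35-fold lower (-1.23 ± 0.25, n = 4, adjusted p = 0.0115), and its call ended without DMSO replicate 1 (adjusted p = 0.0504). The number of lower members was 14 without 40 µg/L replicate 1, 2 without replicate 3 or 4, 1, 4 and 3 without DMSO replicates 1, 2 and 4, and 4 with water as the control. Lens crystallin genes were higher, with 5 of 34 up and 0 down (20 up and 1 down adjusted over the list alone). Their median was 0.48, with an adjusted p of 5.66e-07 (adjusted p = 0.622 with an estimated correlation). Of these crygs1 was 2.2-fold higher (1.14 ± 0.19, adjusted p = 0.00493) and crygm6 1.97-fold higher (0.98 ± 0.23, adjusted p = 0.0234). Against water they stood at 0.77 (adjusted p = 0.0503) and 0.87 (adjusted p = 0.0573), and 0 of the 34 passed the limma test. Crystallins of the list lay lower in DMSO than in water (median -0.13), which makes the rise larger against DMSO than against water. The crystallin count was 20 up and 1 down without 40 µg/L replicate 1, 1 without any other 40 µg/L array or without DMSO replicate 1 or 2, and 2 without DMSO replicate 3. The call of crygm6 ended without 40 µg/L replicate 2, 3 or 4 or DMSO replicate 1 or 2 (adjusted p = 0.0559 to 0.0915).

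The other 6 lists called at 40 µg/L held few changed members, and none of the 8 calls of this comparison held with an estimated correlation. Cardiac muscle genes lay lower (1 of 17 down, 1 adjusted over the list alone, median -0.38, adjusted p = 0.00131, and adjusted p = 0.622 with an estimated correlation). The 1 member was popdc2, a membrane protein gene of muscle, 2.38-fold lower (-1.25 ± 0.33, n = 4, adjusted p = 0.0389). Cartilage, bone and matrix genes lay lower (median -0.25, adjusted p = 0.00213, and adjusted p = 0.622 with an estimated correlation), and 1 of 28 rose and 1 fell (1 and 4 adjusted over the list alone). The osteoblast factor runx2b went against the list (0.78 ± 0.20, adjusted p = 0.0357), and the matrilin gene matn3a fell by 0.94 ± 0.23 (adjusted p = 0.0299). Inflammation genes lay higher (2 of 16 up, 2 adjusted over the list alone, median 0.29, adjusted p = 0.0373, and adjusted p = 0.689 with an estimated correlation). They were the cytokine signalling suppressor socs3a (0.72 ± 0.14, adjusted p = 0.0116) and the prostaglandin synthase ptgs2b (0.64 ± 0.15, adjusted p = 0.0237). Xanthophore and iridophore genes were called lower (1 of 16 down, 2 adjusted over the list alone, median -0.03, adjusted p = 0.0389, and adjusted p = 0.622 with an estimated correlation). The member that fell was gch2, the pteridine synthesis enzyme GTP cyclohydrolase, 3.58-fold lower (-1.84 ± 0.25, adjusted p = 0.00192). Immediate early genes were called higher (2 of 27 up, 3 adjusted over the list alone, median 0.28, adjusted p = 0.0477, and adjusted p = 0.691 with an estimated correlation). These were the phosphatase dusp1 at 0.57 ± 0.15 (adjusted p = 0.0418; its second probe gave -0.19) and btg2 at 0.63 ± 0.17 (adjusted p = 0.0479). Fatty acid metabolism genes were called lower (1 up and 1 down of 27, the same adjusted over the list alone, median -0.12, adjusted p = 0.0488, and adjusted p = 0.691 with an estimated correlation). The hepatic lipase lipca stood at 0.72 ± 0.19 (adjusted p = 0.0387) and the fatty acid transporter cd36 at -1.04 ± 0.28 (adjusted p = 0.0438). Single left-out arrays ended many of these calls. The fatty acid list was lost without DMSO replicate 1 or 3 or 40 µg/L replicate 2, 3 or 4 (adjusted p = 0.0691 to 0.167). The immediate early list was lost without DMSO replicate 3 or 40 µg/L replicate 3 or 4 (adjusted p = 0.131 to 0.337), the inflammation list without 40 µg/L replicate 1 or 3 (0.0771 to 0.171) and the xanthophore list without 40 µg/L replicate 2 or 3 (0.0512 to 0.103). Calls of runx2b, matn3a and ptgs2b ended without DMSO replicate 1, 2 or 3 or 40 µg/L replicate 3 or 4 (adjusted p = 0.0547 to 0.131). Those of dusp1 and btg2 ended without any array but 40 µg/L replicate 1 (adjusted p = 0.0519 to 0.128), and that of popdc2 without any but DMSO replicate 4 and 40 µg/L replicate 1 (0.0751 to 0.123). That of lipca ended without DMSO replicate 1, 2 or 3 or 40 µg/L replicate 2 or 4 (adjusted p = 0.0605 to 0.112), and that of cd36 without DMSO replicate 1, 2 or 4 or 40 µg/L replicate 3 or 4 (0.0672 to 0.157). With water as the control, the cartilage list (adjusted p = 0.072) and the fatty acid list (0.176) were not called, nor were popdc2 (0.0575), runx2b (0.715), matn3a (0.0636), ptgs2b (0.0827), lipca (0.4) and cd36 (0.0706).

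In lists that were not called at 40 µg/L, single genes passed the test. In the p53 and apoptosis list 2 of 30 rose (4 adjusted over the list alone, camera adjusted p = 0.0624), among them the initiator caspase casp9 (0.84 ± 0.15, n = 4, adjusted p = 0.00748). Cell cycle genes had 0 up and 4 of 35 down (1 and 5 adjusted over the list alone, camera adjusted p = 0.0624). They included cyclin D1, ccnd1 (-0.85 ± 0.15, adjusted p = 0.00586), and the replicative helicase gene mcm2 (-1.05 ± 0.23, adjusted p = 0.0178). Of 22 DNA repair genes 3 fell (2 up and 3 down adjusted over the list alone, camera adjusted p = 0.369), with the nucleotide excision repair genes ddb2 (-0.81 ± 0.14, adjusted p = 0.00584) and xpc (-1.13 ± 0.23, adjusted p = 0.0125). Of 30 AhR and xenobiotic genes 3 fell (2 up and 3 down adjusted over the list alone, adjusted p = 0.0545), including the cytochrome P450 gene cyp2ad2 (-1.85 ± 0.42, adjusted p = 0.0217). Of 12 measured genes in the target kinase list 1 rose, prkcz (0.78 ± 0.13, adjusted p = 0.00524; 2 adjusted over the list alone, camera adjusted p = 0.243). It encodes an atypical protein kinase C, a class that PKC412 inhibits weakly if at all, and against water it stood at -0.04 (adjusted p = 0.897). Of 34 neuronal genes 1 rose (1 adjusted over the list alone, adjusted p = 0.431), the neuronal transcription factor neurod1 (1.51 ± 0.23, adjusted p = 0.00344). Leaving out DMSO replicate 1 or 40 µg/L replicate 3 ended the calls of mcm2 and cyp2ad2, and 40 µg/L replicate 4 that of mcm2 (adjusted p = 0.055 to 0.0915).

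Of the remaining lists at 40 µg/L, erythroid genes had 3 of 22 up (3 adjusted over the list alone, camera adjusted p = 0.369). Glycolysis and hypoxia genes had 3 up and 2 down of 36 (the same adjusted over the list alone, adjusted p = 0.425). Heat shock genes had 1 of 33 down (2 up and 4 down adjusted over the list alone, adjusted p = 0.369). Cholesterol synthesis had 1 of 24 down (2 adjusted over the list alone, adjusted p = 0.161). The glucocorticoid list had 1 of 30 up (0 adjusted over the list alone, adjusted p = 0.0624). Keratins had 1 of 24 up (adjusted p = 0.592), liver genes 1 of 32 up (adjusted p = 0.217) and myeloid genes 1 of 14 up (adjusted p = 0.707), with 1 each adjusted over the list alone. Vitellogenin genes had 0 of 7 and thyroid axis genes 0 of 9 changed by limma (1 up and 1 down adjusted over the list alone, camera adjusted p = 0.369 for both). Vascular (15), oxidative stress (29), skeletal muscle (33), exocrine pancreas (22) and melanophore (14) genes had 0 changed by limma by either adjustment, and unadjusted p under 0.05 in 0, 4, 11, 1 and 1 members. Median, mean and test differed in sign for the cell cycle (median 0.03, mean -0.13, test down), DNA repair (0.05, -0.04, down), photoreceptor (0.15, -0.01, down), and oxidative stress lists (0.01, -0.04, down). They also differed for the heat shock (0.01, -0.03, down), neuronal (0.06, -0.01, down), myeloid (-0.02, 0.02, down) and thyroid lists (0.07, -0.04, down). By fry 4 lists moved one way on balance: the intestinal (adjusted p = 0.0351), lens (0.0462), p53 (0.00936) and target kinase lists (0.00936).

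In all, 1525 probes changed at 40 µg/L against DMSO, 1106 higher and 419 lower (72.5% higher, 7107 at an unadjusted p under 0.05), with 698 changed at least 2-fold. The 4 arrays of each group did not overlap for 1341 of them and for 3450 of the 30798 tested, where chance gives 2.86%. Large changes of named genes also included asah2, a neutral ceramidase gene (-2.23 ± 0.37, n = 4, adjusted p = 0.00473), and osgn1 (-2.06 ± 0.35, adjusted p = 0.00485). Higher were asb15b (2.13 ± 0.33, adjusted p = 0.00349, above background on 3 of 4 DMSO arrays) and the interleukin receptor gene il7r (1.88 ± 0.22, adjusted p = 0.000798). So were the interferon-responsive gene ifi27.1 (1.71 ± 0.37, adjusted p = 0.0164, but 0.0665 without DMSO replicate 1) and the parathyroid hormone gene pth1a (1.61 ± 0.28, adjusted p = 0.00553). The vessel ligand gene angpt2b, the uridine-cytidine kinase gene uck1 and the Ran exchange factor gene rcc1 were 3.63-, 3.73- and 3.29-fold higher than in DMSO (1.86 ± 0.24, 1.90 ± 0.22 and 1.72 ± 0.21). Against water they stood at 0.17, 0.11 and 0.37 (adjusted p = 0.701, 0.794 and 0.332). Second probes of uck1 and rcc1 gave 0.30 and -0.42. The share of higher calls was 53.9% of 1628 with median centring, 47.7% of 1462 with quantile normalisation and 85.6% of 4134 with normexp from negative controls. The count was 5621 without 40 µg/L replicate 1, 697 and 721 without replicates 3 and 4, and 406 and 665 without DMSO replicates 1 and 2.

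At 2 µg/L PKC412, the clock repressor genes nr1d1, per1b and cry2 were lower than in DMSO, and 8 of 22 exocrine pancreas genes were higher (camera adjusted p = 1.15e-11 for the list, and adjusted p = 0.533 with an estimated correlation). The repressor nr1d1 was 14.7-fold lower (-3.88 ± 0.43 (SE), n = 4, adjusted p = 0.00048) and per1b 4.39-fold lower (-2.13 ± 0.22, adjusted p = 0.000269). The cryptochrome repressor cry2 was 4.38-fold lower (-2.13 ± 0.29, adjusted p = 0.00217) and tefa 3.29-fold lower (-1.72 ± 0.16, adjusted p = 0.000207). The deubiquitinase gene usp21 was 4.35-fold lower (-2.12 ± 0.19, adjusted p = 0.000207) and eevs 4.68-fold lower (-2.22 ± 0.39, adjusted p = 0.0109). The digestive elastase gene cela1.3 was 3.42-fold higher (1.77 ± 0.36, adjusted p = 0.0264) and cel.1, the bile salt-dependent lipase gene, 3.87-fold higher (1.95 ± 0.42, adjusted p = 0.0319). The first 6 of these calls held with every array left out in turn. Those of cela1.3 and cel.1 ended without 2 µg/L replicate 1, 2 or 3 or DMSO replicate 1, 2 or 4 (adjusted p = 0.0737 to 0.11).

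Of 27 clock genes 6 rose and 9 fell at 2 µg/L (8 and 13 adjusted over the list alone). Their median was -0.40, with an adjusted p of 0.00442 by camera (adjusted p = 0.533 with an estimated correlation) and of 0.00864 by fry. The light-responsive cryptochrome gene cry3b went against the list (1.97 ± 0.39, n = 4, adjusted p = 0.0222, and 0.0619 to 0.0861 without 2 µg/L replicate 2, 3 or 4 or DMSO replicate 1, 2 or 4). Higher clock genes numbered 2 or 3 without any 1 array of the comparison except DMSO replicate 3, and lower ones 6 without 2 µg/L replicates 1, 2 and 3 or DMSO replicates 1, 2 and 4. With water as the control 7 rose and 12 fell. Among 41 photoreceptor genes 3 rose and 7 fell (10 and 11 adjusted over the list alone, adjusted p = 0.152). Those lower included arr3b (-1.93 ± 0.25, adjusted p = 0.00155), the cone opsin kinase grk7a (-1.49 ± 0.20, adjusted p = 0.00173) and pde6c (-1.16 ± 0.13, adjusted p = 0.00048). Without any 1 array of the comparison except DMSO replicate 3, 0 photoreceptor genes rose by limma and 5 to 7 fell. The repair genes xpc (-1.55 ± 0.23, adjusted p = 0.00398) and ddb2 (-0.95 ± 0.14, adjusted p = 0.00398) were the 2 of 22 DNA repair genes that fell (1 up and 2 down adjusted over the list alone). Among 36 glycolysis and hypoxia genes 1 rose and 1 fell (2 and 2 adjusted over the list alone). These were ndrg1b (2.02 ± 0.34 for its strongest probe, adjusted p = 0.00895) and the mitochondrial gene higd1a (-1.37 ± 0.21, adjusted p = 0.00436). In the xanthophore and iridophore list 1 of 16 rose and 1 fell (2 and 2 adjusted over the list alone), the latter being gch2 (-1.50 ± 0.25, adjusted p = 0.00807).

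Exocrine pancreas genes were higher at 2 µg/L, with 8 of 22 up (19 adjusted over the list alone). Their median was 0.93 (camera adjusted p = 1.15e-11, fry adjusted p = 0.0147, and adjusted p = 0.533 with an estimated correlation). Among them were the elastase gene cela1.5 (1.03 ± 0.21, n = 4, adjusted p = 0.0258), cpb1, a carboxypeptidase B gene (1.83 ± 0.42, adjusted p = 0.0439), and ela3l (1.83 ± 0.44, adjusted p = 0.0491). Without 2 µg/L replicate 1, 2 or 3 or DMSO replicate 1, 2 or 4, 0 of the 22 passed the limma test. These calls ended (adjusted p = 0.0737 to 0.156 over the 5 genes named here and above), and that of ela3l also ended without 2 µg/L replicate 4 (0.0565). The list itself was called in each case. Without 40 µg/L replicate 2, which enters only the shared spread, 12 of the 22 passed, and 13 did with water as the control.

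Of the other lists called at 2 µg/L, myeloid genes lay higher (2 of 14 up, 8 adjusted over the list alone, median 0.54, adjusted p = 0.000597). They were the actin-bundling gene lcp1 (0.88 ± 0.19, n = 4, adjusted p = 0.0338) and cpa5, a carboxypeptidase gene of mast cells (1.59 ± 0.35, adjusted p = 0.0374). The gene cpa5 is also in the exocrine pancreas list, so its call counts in both lists. AhR and xenobiotic genes lay higher (1 of 30 up, 4 adjusted over the list alone, median 0.29, adjusted p = 0.00212), the member being the cytochrome P450 gene cyp3a65 (0.86 ± 0.20, adjusted p = 0.0432). The glucocorticoid list lay higher (1 of 30 up, 4 up and 1 down adjusted over the list alone, median 0.24, adjusted p = 0.0178) with the growth factor-binding gene igfbp1b (1.42 ± 0.28, adjusted p = 0.0213). Each of these had an adjusted p = 0.533 with an estimated correlation. Fatty acid genes lay higher (1 of 27 up by either adjustment, median 0.21, adjusted p = 0.019, and adjusted p = 0.623 with an estimated correlation) with lipca (0.85 ± 0.19, adjusted p = 0.0362). Neuronal genes lay lower as a list (median -0.28, adjusted p = 0.000161, and adjusted p = 0.533 with an estimated correlation), but the 1 of 34 that passed by either adjustment, neurod1, rose (1.16 ± 0.23, adjusted p = 0.0232). The call of lcp1 ended without any array but DMSO replicate 3 (adjusted p = 0.0518 to 0.122), as did that of igfbp1b (0.0559 to 0.0798). Those of cyp3a65 and lipca ended without any 1 array (adjusted p = 0.0606 to 0.145). The call of cpa5 ended without 2 µg/L replicate 1, 2 or 3 or DMSO replicate 1, 2 or 4 (adjusted p = 0.0943 to 0.132), and that of neurod1 without 2 µg/L replicate 2, 3 or 4 or DMSO replicate 1, 2 or 4 (0.0709 to 0.0861). The fatty acid list was lost without 2 µg/L replicate 3 (adjusted p = 0.0758) and the glucocorticoid list without DMSO replicate 3 (0.121) or 2 µg/L replicate 4 (0.0524). Against water lipca stood at 0.41 (adjusted p = 0.163).

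A further 7 lists were called at 2 µg/L with 0 members past the limma test over all probes. Lens crystallins lay lower (median -0.34 over 34, adjusted p = 1.53e-05, and adjusted p = 0.533 with an estimated correlation), and liver and plasma protein genes higher (0.66 over 32, adjusted p = 7.05e-05, and 0.688 with an estimated correlation). Cardiac muscle genes lay higher (0.43 over 17, 3 up adjusted over the list alone, adjusted p = 0.00072, and adjusted p = 0.533 with an estimated correlation). So did melanophore genes (0.47 over 14, 6 up adjusted over the list alone, adjusted p = 0.000751, and 0.533 with an estimated correlation). Oxidative stress genes (0.21 over 29, adjusted p = 0.00591, and 0.708 with an estimated correlation) lay higher. So did inflammation genes (0.44 over 16, 5 up and 1 down adjusted over the list alone, adjusted p = 0.019, and 0.54) and p53 genes (0.25 over 30, adjusted p = 0.036, and 0.533). Unadjusted p was under 0.05 in 7 lens, 12 liver, 7 cardiac, 8 melanophore, 6 oxidative stress, 8 inflammation and 12 p53 genes. The inflammation list was lost without 2 µg/L replicate 4 (adjusted p = 0.0504) and the p53 list without DMSO replicate 1 (0.0725) or 2 µg/L replicate 4 (0.0704). By fry the p53 list moved up (adjusted p = 0.0147). None of the 14 list calls of this comparison held with an estimated correlation. Among lists not called, 1 of 24 cholesterol genes fell (1 up and 2 down adjusted over the list alone). By limma 0 of 19 intestinal genes passed (2 up and 1 down adjusted over the list alone, median 0.20, adjusted p = 0.382, 7 at an unadjusted p under 0.05). Erythroid genes had a median of 0.12, a mean of 0.02 and a downward test.

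The 2 µg/L comparison had 486 changed probes, 243 higher and 243 lower (6119 at an unadjusted p under 0.05), of which 235 changed at least 2-fold. The groups did not overlap for 484 of them and for 8822 of all tested, against 2.86% by chance. Further named genes were asb15b (2.24 ± 0.33, n = 4, adjusted p = 0.00364, above background on 3 of 4 DMSO arrays), the neuronal calcium sensor gene ncaldb (-1.58 ± 0.23, adjusted p = 0.00307) and otud7b (-1.86 ± 0.45, adjusted p = 0.0495). The call of otud7b ended without any 1 array of the comparison (adjusted p = 0.0581 to 0.169), and its probes spanned -1.86 to 0.35. With median centring 326 probes changed, 37.7% of them higher. The count was 169, 112, 109 and 207 without 2 µg/L replicates 1 to 4, 122, 145 and 148 without DMSO replicates 1, 2 and 4, and 1941 without 40 µg/L replicate 2.

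**Figure D2:**
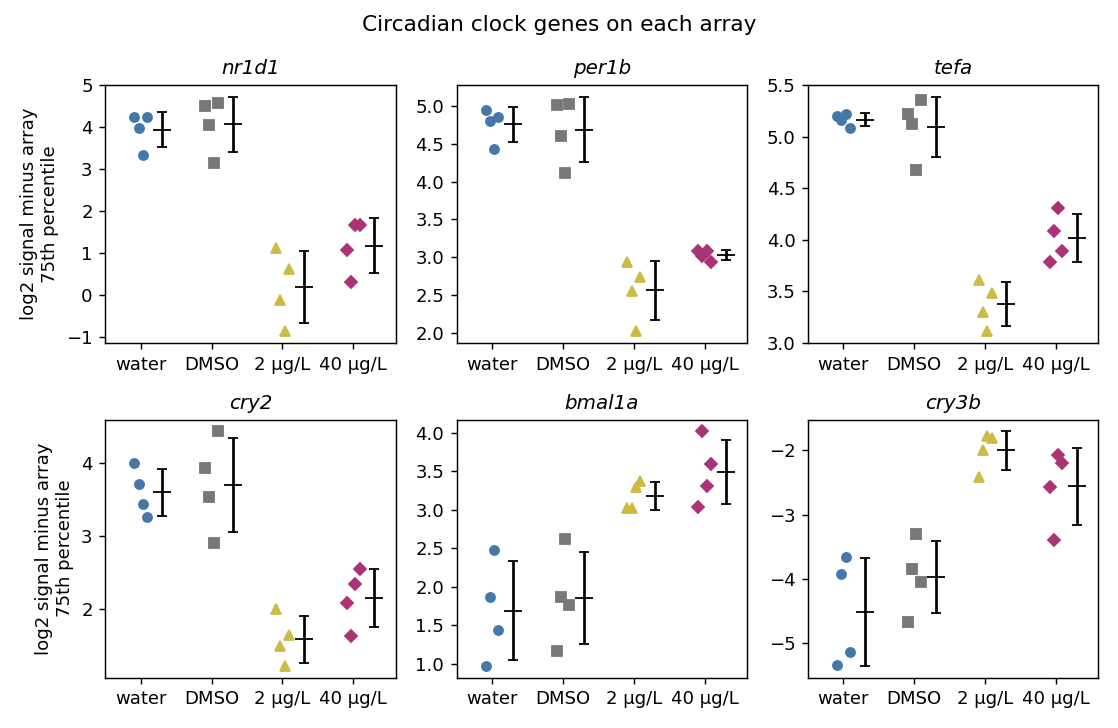
Normalised log2 signal of 6 clock genes (nr1d1, per1b, tefa, cry2, bmal1a and cry3b) by group, relative to the 75th percentile of each array. Points are the 4 arrays of a group and black bars the mean ± SD; nr1d1 was 14.7-fold lower than DMSO at 2 µg/L and 7.4-fold lower at 40 µg/L.

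Between the doses, lists of the digestive tract and heart were lower at 40 than at 2 µg/L, and lens crystallins were higher (camera adjusted p = 2.74e-07 or less, and adjusted p = 0.451 for each with an estimated correlation). The monoacylglycerol acyltransferase gene mogat2 was 5.82-fold lower (-2.54 ± 0.44 (SE), n = 4, adjusted p = 0.00619) and cpb1 5.31-fold lower (-2.41 ± 0.42, adjusted p = 0.00631). The lipase gene cel.1 was 5.24-fold lower (-2.39 ± 0.42, adjusted p = 0.00616) and cela1.3 4.71-fold lower (-2.24 ± 0.36, adjusted p = 0.00513). The natriuretic peptide gene nppa was 3.4-fold lower (-1.76 ± 0.37, adjusted p = 0.0105). The crystallin gene crygm2a was 3.22-fold higher (1.69 ± 0.29, adjusted p = 0.00587). Each of these calls held with every array of the comparison left out in turn. By an ordinary test per probe 3 of the 50 gene calls named for this comparison held, and with only the 8 arrays compared 42 did.

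Of 22 exocrine pancreas genes 14 fell and 0 rose at 40 against 2 µg/L (16 down adjusted over the list alone, median -1.05, camera adjusted p = 5.87e-11, fry 0.0046, and adjusted p = 0.451 with an estimated correlation). Of 19 intestinal genes 15 fell and 0 rose (16 down adjusted over the list alone, median -1.13, adjusted p = 5.06e-10, fry 0.00608, and adjusted p = 0.451 with an estimated correlation). Among them were the chitinase genes chia.1 (-1.71 ± 0.32, n = 4, adjusted p = 0.00769) and chia.2 (-1.21 ± 0.22, adjusted p = 0.00683) and the meprin gene mep1ba (-2.18 ± 0.43, adjusted p = 0.00867). Of 17 cardiac genes 11 fell and 0 rose (1 up and 15 down adjusted over the list alone, median -0.71, adjusted p = 2.74e-07, fry 0.0046, and adjusted p = 0.451 with an estimated correlation). Among these were the atrial myosin light chain gene myl7 (-1.17 ± 0.23, adjusted p = 0.00863), cardiac troponin C, tnnc1a (-1.16 ± 0.20, adjusted p = 0.00572), and the transcription factor gata6 (-1.46 ± 0.30, adjusted p = 0.00951). Of 34 lens crystallins 26 rose and 0 fell (27 up and 1 down adjusted over the list alone, median 0.83, adjusted p = 5.02e-12, fry 0.0043, and adjusted p = 0.451 with an estimated correlation). These included crygs1 (1.54 ± 0.19, adjusted p = 0.00163) and crygm7 (1.47 ± 0.26, adjusted p = 0.00676). Without 2 µg/L replicate 3 the counts were 9 intestinal and 7 cardiac genes lower and 12 crystallins higher, and without 40 µg/L replicate 4 the cardiac count was also 7. The default normexp correction called 0 members of the first 3 lists, and 1 probe in all. The directions of the 4 list medians were the same with quantile normalisation and with both normexp fits.

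**Figure D3:**
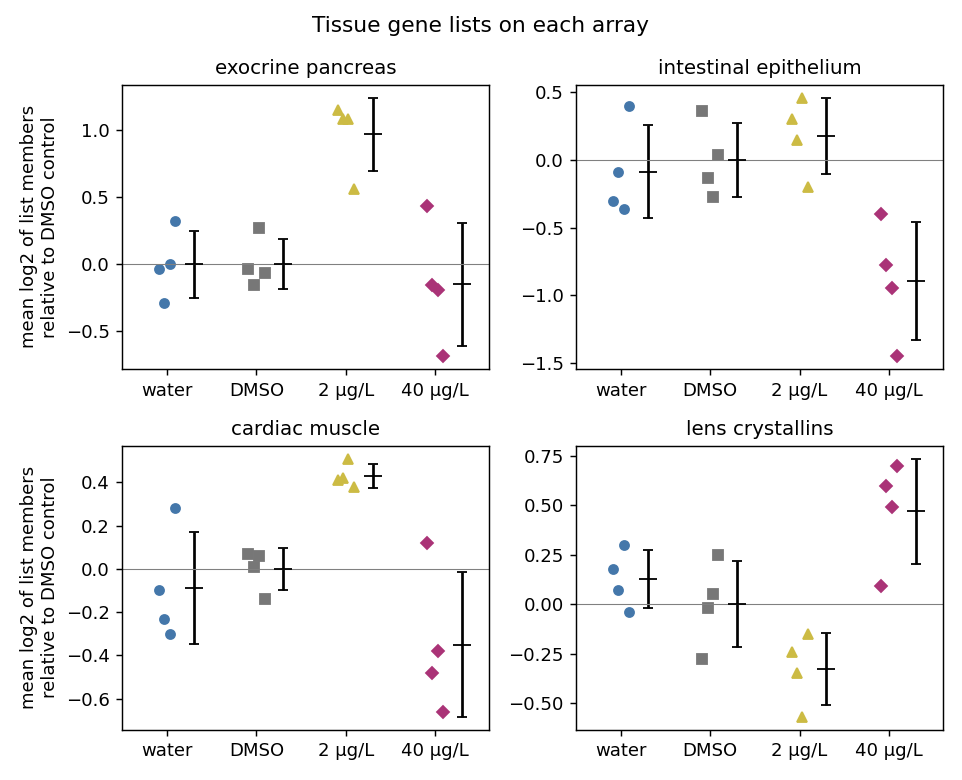
Mean log2 change of the exocrine pancreas, intestinal epithelium, cardiac muscle and lens crystallin lists on each array, relative to the mean of the DMSO arrays. Points are arrays and black bars the mean ± SD of 4; the pancreas list lay at 0.97 ± 0.28 at 2 µg/L and -0.15 ± 0.46 at 40 µg/L.

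Several lists of liver and metabolism were lower at 40 than at 2 µg/L. Liver and plasma protein genes had 7 of 32 down (7 adjusted over the list alone, median -0.66, camera adjusted p = 1.64e-05, and adjusted p = 0.614 with an estimated correlation). Among them were the apolipoprotein genes apoa1a (-2.01 ± 0.41, n = 4, adjusted p = 0.0095), apoa1b (-2.07 ± 0.39, adjusted p = 0.00779) and apobb.1 (-1.22 ± 0.25, adjusted p = 0.00973). AhR and xenobiotic genes had 1 up and 12 down of 30 (2 and 14 adjusted over the list alone, median -0.50, adjusted p = 3.83e-05, and adjusted p = 0.451 with an estimated correlation). Those lower included cyp3a65 (-1.32 ± 0.20, adjusted p = 0.00313) and the glucuronosyltransferase ugt1a1 (-1.54 ± 0.31, adjusted p = 0.00969). Fatty acid genes had 7 of 27 down (7 adjusted over the list alone, median -0.39, adjusted p = 0.000305, and adjusted p = 0.451 with an estimated correlation). They included the elongase elovl2 (-1.94 ± 0.37, adjusted p = 0.00811) and the desaturase fads2 (-1.25 ± 0.27, adjusted p = 0.0114). Oxidative stress genes had 4 of 29 down (3 adjusted over the list alone, median -0.27, adjusted p = 0.00477, and adjusted p = 0.614 with an estimated correlation). Of these, the catalase gene cat fell (-1.07 ± 0.24, adjusted p = 0.0127), as did the glutathione transferase gsto2 (-0.82 ± 0.20, adjusted p = 0.0162, but 0.0605 and 0.0518 without 2 µg/L replicate 3 and 40 µg/L replicate 4). Lower liver genes numbered 18 without 40 µg/L replicate 1, 4 without 40 µg/L replicate 2 or 2 µg/L replicate 1, and 3 without 2 µg/L replicate 3. Lower AhR genes numbered 7, 6 and 3 without 2 µg/L replicates 1, 2 and 3, and 7 and 5 without 40 µg/L replicates 3 and 4. Lower fatty acid genes numbered 3 without 2 µg/L replicate 3 and 4 without 40 µg/L replicate 4.

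Pigment cell and myeloid lists were also lower at 40 than at 2 µg/L. Melanophore genes had 5 of 14 down (5 adjusted over the list alone, median -0.43, camera adjusted p = 0.00158, and adjusted p = 0.544 with an estimated correlation). They included the melanosome matrix genes pmelb (-2.33 ± 0.45, n = 4, adjusted p = 0.00867, above background on 3 of 4 arrays at 40 µg/L), and pmela (-1.27 ± 0.30, adjusted p = 0.0142, but 0.0525 without 2 µg/L replicate 3). Xanthophore and iridophore genes had 3 of 16 down (3 adjusted over the list alone, median -0.30, adjusted p = 0.0231, and adjusted p = 0.451 with an estimated correlation). Among the 3 were the sugar transporter slc2a15b (-1.0 ± 0.21, adjusted p = 0.0106) and the purine synthesis gene paics (-1.20 ± 0.29, adjusted p = 0.0153). The list was lost without 40 µg/L replicate 3 (0.0511). Myeloid genes had 1 up and 7 down of 14 (1 and 8 adjusted over the list alone, median -0.73, adjusted p = 0.0017, and adjusted p = 0.58 with an estimated correlation). Of these lcp1 fell (-0.93 ± 0.19, adjusted p = 0.00973), as did cpa5 (-2.52 ± 0.42, adjusted p = 0.00561, and -1.96 for the probe used in the list), which is also in the exocrine pancreas list. The NADPH oxidase gene cybb rose (1.16 ± 0.19, adjusted p = 0.00561), but its second probe gave -1.36 and was called the other way. Lower melanophore genes numbered 2, 2 and 1 without 2 µg/L replicates 1 to 3 and 3, 3 and 2 without 40 µg/L replicates 2 to 4. Lower myeloid genes numbered 3, 4 and 2 without 2 µg/L replicates 1 to 3 and 4 and 2 without 40 µg/L replicates 3 and 4.

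Immediate early genes were higher at 40 than at 2 µg/L (7 of 27 up, 7 up and 1 down adjusted over the list alone, median 0.32, camera adjusted p = 0.00741, and adjusted p = 0.614 with an estimated correlation). They included the MAP kinase phosphatase genes dusp2 (0.74 ± 0.22, n = 4, adjusted p = 0.0298), dusp5 (0.61 ± 0.18, adjusted p = 0.0301) and dusp6 (0.60 ± 0.19, adjusted p = 0.0346). Neuronal genes were higher too (5 of 34 up, 0 adjusted over the list alone, where 10 had an unadjusted p under 0.05, median 0.29, adjusted p = 0.0173, and adjusted p = 0.614 with an estimated correlation). Those higher included the stathmin gene stmn1b (0.54 ± 0.17, adjusted p = 0.0362) and the neuronal enolase eno2 (0.46 ± 0.15, adjusted p = 0.0374), whose second probes gave -0.11 and -0.02. Both lists were lost without 40 µg/L replicate 4 (adjusted p = 0.0902 and 0.134). Calls of dusp5 and dusp6 ended without 2 µg/L replicate 1, 2 or 3 or 40 µg/L replicate 2, 3 or 4. Those of dusp2 and stmn1b ended without any array but 40 µg/L replicate 1, and that of eno2 without any but 40 µg/L replicates 1 and 2 (0.0506 to 0.109 over the 5 genes). Without single 2 µg/L arrays 0, 0, 1 and 3 immediate early genes rose by limma, and without 40 µg/L replicates 1 to 4 the counts were 13, 3, 0 and 0. For neuronal genes these were 1, 0, 0 and 1, and 11, 1, 0 and 0. None of the 13 list calls of this comparison held with an estimated correlation. By fry 13 lists moved one way on balance, among them the clock (adjusted p = 0.0156) and glycolysis lists (0.0491), which camera did not call, and not the liver list (0.105) or the oxidative stress list.

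Among lists not called between the doses, 4 of 27 clock genes rose (4 adjusted over the list alone, median 0.32, camera adjusted p = 0.0928), including the period gene per1a (1.03 ± 0.23, n = 4, adjusted p = 0.0126). Of 28 cartilage genes 3 rose and 8 fell (3 and 9 adjusted over the list alone, adjusted p = 0.0928). The factor runx2b stood at 1.11 ± 0.20 (adjusted p = 0.00686) and the chondrocyte factor sox9b at -1.03 ± 0.23 (adjusted p = 0.0126). Of 36 glycolysis and hypoxia genes 6 rose and 1 fell (3 and 1 adjusted over the list alone), including the glucose transporter slc2a1a (0.95 ± 0.16, adjusted p = 0.00593). Of 12 target kinases 2 rose and 1 fell by either adjustment, with prkcz at 0.91 ± 0.13 (adjusted p = 0.00298). Photoreceptor genes had 6 up and 1 down of 41 (5 and 1 adjusted over the list alone). Inflammation genes had 3 up and 0 down of 16 (the same adjusted over the list alone, median -0.13, adjusted p = 0.941). Median, mean and test differed in sign for the DNA repair (0.09, -0.03, down), skeletal muscle (0.06, -0.10, down), target kinase (-0.06, -0.05, up), p53 (0.02, -0.004, down) and thyroid lists (-0.15, 0.002, down).

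Between the doses 7318 probes changed, 3688 higher and 3630 lower (50.4% higher, 13021 at an unadjusted p under 0.05), and 2558 changed at least 2-fold. The groups did not overlap for 4890 of them and for 7100 of all tested, against 2.86% by chance. Other named genes with large changes were uck1 (1.93 ± 0.22, n = 4, adjusted p = 0.000745), rcc1 (1.96 ± 0.21, adjusted p = 0.000745, second probe -0.06) and angpt2b (1.81 ± 0.24, adjusted p = 0.00185). Further ones were pth1a (1.91 ± 0.28, adjusted p = 0.0029), asah2 (-2.29 ± 0.37, adjusted p = 0.00513), the amino acid transporter slc38a4 (2.45 ± 0.56, adjusted p = 0.0129) and otud7b (2.09 ± 0.45, adjusted p = 0.0106). The chromatin regulators atf7ip (1.85 ± 0.44, adjusted p = 0.0144) and epc1b (1.76 ± 0.45, adjusted p = 0.0188) and ypel1 (1.78 ± 0.45, adjusted p = 0.0182) were also higher. Calls of these 3 ended without 2 µg/L replicate 3, those of epc1b and ypel1 also without 40 µg/L replicate 4, and that of ypel1 without 40 µg/L replicate 3 (0.0505 to 0.0629). Other probes of slc38a4, otud7b and atf7ip went as low as -0.70, -0.25 and -0.90. With normexp from negative controls 76.3% of 11971 calls were higher. The count was 3540, 2872, 1469 and 4325 without 2 µg/L replicates 1 to 4, and 13369, 3722, 3598 and 2524 without 40 µg/L replicates 1 to 4.

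Against water, the DMSO controls had lower signal for 13 named genes and higher signal for 0. The genes uck1, angpt2b and rcc1 were 3.44-, 3.22- and 2.55-fold lower in DMSO (-1.78 ± 0.22, -1.69 ± 0.24 and -1.35 ± 0.21 (SE), n = 4, adjusted p = 0.00214, 0.0042 and 0.00924). The second probe of uck1 gave 0.07. The ubiquitin ligase adaptor gene klhl36 was 2.07-fold lower (-1.05 ± 0.12, adjusted p = 0.00152). The embryonic globin gene hbbe3 (-1.02 ± 0.16, adjusted p = 0.00924) and the haem synthesis gene urod (-0.73 ± 0.11, adjusted p = 0.00803) were the 2 of 22 erythroid genes that fell (3 adjusted over the list alone). The kinase gene prkcz (-0.82 ± 0.13, adjusted p = 0.0105, but 0.0546 without DMSO replicate 3) was the 1 of 12 target kinases (1 adjusted over the list alone). In all 154 probes changed, 1 higher and 153 lower (1388 at an unadjusted p under 0.05), 117 of them at least 2-fold. The groups did not overlap for 153 of these. Over all 30798 tested probes they did not overlap for 982, a share close to the 2.86% that chance gives. With only the 8 arrays compared 11 probes changed, and by an ordinary test per probe 0. With quantile normalisation 73 changed, 15.1% of them higher, and with normexp from negative controls 13 changed. The count was 56, 71 and 60 without DMSO replicates 1 to 3, and 63, 235, 81 and 84 without water replicates 1 to 4.

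**Figure D4:**
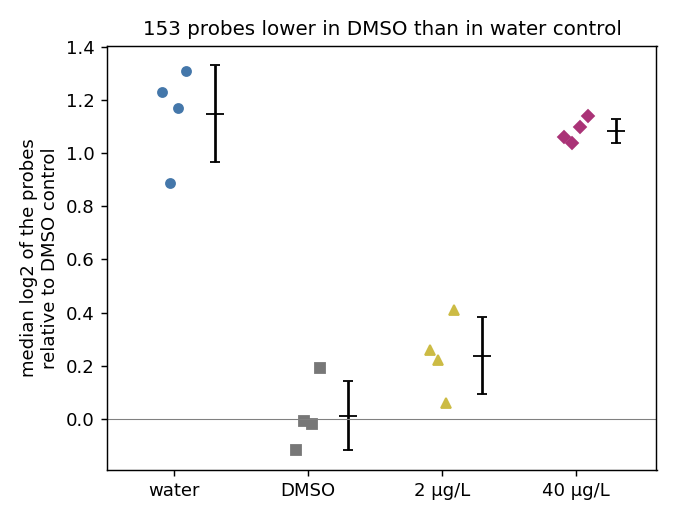
Median log2 signal over the 153 probes lower in DMSO than in water, on each of the 16 arrays, relative to the mean of the DMSO arrays. Points are arrays and black bars the mean ± SD of 4; water arrays lay between 0.89 and 1.31, DMSO arrays between -0.12 and 0.19, 2 µg/L arrays between 0.06 and 0.41 and 40 µg/L arrays between 1.04 and 1.14.

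No clock gene differed between DMSO and water by limma (0 of 27, 2 at an unadjusted p under 0.05, camera adjusted p = 0.87), with a median of -0.04, a mean of -0.02 and an upward test. Camera called 7 lists, none of which had a member past the limma test, and none held with an estimated correlation. Liver genes lay higher in DMSO (31 of 32 above 0, median 0.24, adjusted p = 1.15e-06). So did immediate early (0.10 over 27, 9.75e-05), AhR (0.09 over 30, 0.00406), glucocorticoid (0.16 over 30, 0.00406), inflammation (0.18 over 16, 0.018) and cartilage genes (0.09 over 28, 0.0214). Each had an adjusted p = 0.881 with an estimated correlation, and lens crystallins, which lay lower (-0.13 over 34, adjusted p = 0.00406), had 0.911. An unadjusted p under 0.05 was met by 1 liver, 2 immediate early, 1 AhR, 2 glucocorticoid, 1 inflammation, 1 cartilage and 2 lens genes. Without water replicate 3 none of the 7 was called (adjusted p = 0.0514 to 0.421). Without water replicate 2 the liver (0.398), AhR (0.0962), glucocorticoid (0.342) and inflammation lists (0.555) were lost. Without DMSO replicate 1 the AhR (0.336), cartilage (0.227), glucocorticoid (0.11) and lens lists (0.822) were lost. Further losses were, without water replicate 1, the cartilage (0.109) and lens lists (0.0682), without water replicate 4, the cartilage list (0.125), and without DMSO replicate 3, the inflammation list (0.0583). Under the default normexp correction the immediate early median was -0.01. Median, mean and test also differed in sign for the erythroid (0.04, -0.09, down) and target kinase lists (0.04, 0.004, down). They did so too for the photoreceptor (-0.03, -0.02), pancreas (-0.002, 0.003), oxidative stress (-0.01, 0.03), glycolysis (-0.03, 0.03), thyroid (-0.01, -0.03) and vitellogenin lists (0, -0.02), each with an upward test.

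The 2 doses shared 176 changed probes in the same direction, 88 higher and 88 lower, with 0 in opposite directions. Lists of these sizes drawn independently would share 12, and unchanged groups simulated against the same DMSO arrays shared 0.01 (0 to 1 over 100 simulations). The log2 changes at the 2 doses correlated at 0.026 across probes, which are not independent, against 0.499 (0.481 to 0.513) in the simulation, and their covariance was 0.0051 against 0.0377 (0.0363 to 0.0398), a difference of -0.0326. The share of probes with the same sign was 47.3%, against 66.7% simulated. The simulation took its spread from all 4 groups together. DMSO arrays lay on average 0.379 to 0.506 (root mean square log2 difference) from their own group, and 40 µg/L arrays 0.595 to 0.873. The simulated correlation and covariance may thus be too high for these DMSO arrays. Probes were drawn independently and without a slide effect, so calls shared through a shift of the DMSO slide were not simulated. With the DMSO arrays split so that each dose had 2 of its own, the correlation ranged from -0.292 to 0.193 and the shared calls from 14 to 47. With water as the control for 40 µg/L, 152 calls were shared in the same direction and 0 in opposite directions (5.3 for independent lists). With water as the control for 2 µg/L the numbers were 233 and 233 (59.6 for independent lists in the same direction).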

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

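All tests of this part were chosen after the results were seen, except the 2 tests between the doses on probes of the same level, whose expected outcomes were written down first. Arrays that stood apart from the other 3 of their group were found by the gap to the nearest array divided by the range of the group, against Dixon's critical value. Chance passes this value in about 1 in 20 groups, and here it was passed by 2 of 28 groups for array measures, 9 of 136 for gene lists and 18 of 388 for named genes, close to that share.

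Clock genes differed between both PKC412 groups and both control groups. An index of 9 activators minus 12 repressors, set up after the clock genes had been seen to change, was computed per array. It lay at 0 ± 0.58 in DMSO, -0.05 ± 0.39 in water, 2.3 ± 0.24 at 2 µg/L and 1.86 ± 0.17 at 40 µg/L (SD, n = 4). The exact permutation p was 0.0286 for each dose against DMSO, the smallest possible, and 0.118 after adjustment over 136 tests. A graded effect of dose was neither shown nor excluded, since 40 µg/L lay -0.44 from 2 µg/L (exact permutation p = 0.0571). A different time of day at collection, which is not given, could also part the groups: control arrays lay up to 1.25 apart on the index, between the replicate spread and the shift of the exposed groups, and group and slide coincide. An effect of PKC412 on the clock and a shared collection time cannot be told apart.

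The 153 probes lower in DMSO than in water formed a pattern in which water and 40 µg/L arrays lay high and DMSO and 2 µg/L arrays low. Of these, 118 were higher at 40 than at 2 µg/L, a comparison of other arrays, against 18.3 for independent lists. They were dim (median level -4.28, against -1.4 for all tested probes). The 6012 other probes of the same level shifted by 0 between the doses against 0.9 for the pattern. Among probes that passed the filter, this argues against background for the difference between the doses. Probes that failed the filter were not in this check. Without the filter the median change of all probes between the doses was 0.168, against 0.035 with it. For DMSO against water, background stays open. The other probes shifted by 0.06 against -1.12, yet the negative control spots spread more on the water arrays. Without the filter on dim probes 3061 were lower in DMSO. The median distance to the nearest other such probe was 7.28 spots, within the 6.4 to 9.85 of 500 random sets, which argues against a local defect. A shared egg or labelling batch of the water and 40 µg/L groups may account for the 118. With each group on its own slide, such a batch cannot be told apart from a response to DMSO that is absent or offset at 40 µg/L. The labels do not say whether the PKC412 beakers held DMSO.

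Of the 58 pancreatic, intestinal and cardiac genes 40 were lower at 40 than at 2 µg/L. Relative to DMSO, the pancreas list lay at 0.97 at 2 µg/L and -0.15 at 40 µg/L. The intestinal list lay at 0.18 and -0.9, and the cardiac list at 0.43 and -0.35. For the pancreas list the difference thus lay mostly in the 2 µg/L arrays, and for the intestinal list mostly in the 40 µg/L arrays. No 1 array at 40 µg/L explains the lower genes: 46, 38, 33 and 30 were lower without replicates 1 to 4, and 32, 32, 27 and 37 without the 2 µg/L replicates. Lower signal at 40 µg/L in general does not explain it either, since 11540 other probes of the same level had a median change of 0.09 against -1.04 for the 58. Quantile normalisation gave 45, normexp from negative controls 41, and the default normexp, which called 1 probe in all, 0. Whether these tissues respond to dose or the slides differ, in general signal or otherwise, was not settled, and both stay open.

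The 8 arrays of a comparison can be divided into 4 and 4 in 35 ways. For 2 µg/L against DMSO 1 division, the real one, gave 486 or more changed probes (highest other 0). Between the doses the real division was again alone, at 7318. The highest other gave 2604 (2 µg/L replicates 1 to 3 and 40 µg/L replicate 1 on one side). The same holds for DMSO against water, with 1 division at 154 or more and the highest other at 2. A share of 1 in 35 is the smallest possible, and it was not adjusted over the comparisons. Mixed divisions also move group differences into the spread of the fit, which can lower their counts. A slide effect would set the real division apart too. These counts therefore do not by themselves exclude chance. For 40 µg/L against DMSO the real division was not alone: 2 divisions gave 1525 or more. The highest other gave 5604, with DMSO replicates 1 to 3 and 40 µg/L replicate 1 on one side. A division that calls several times the real count points to a structure of the samples. Over all probes, the root mean square difference of 40 µg/L replicate 1 averaged 0.565 on the log2 scale from DMSO arrays, 0.781 from its own group (1.06 from replicate 2) and 0.445 from 2 µg/L arrays. The 4 water arrays and 40 µg/L replicate 3 also lay nearer on average to DMSO arrays than to their own group (for example 0.486 against 0.534 for water replicate 1, and 0.59 against 0.595 for 40 µg/L replicate 3). On the clock index 40 µg/L replicate 1 lay at 2.08, within the 2 µg/L arrays (2.04 to 2.6) and above the other 40 µg/L arrays (1.67 to 1.89). On the 153 probes it lay at 1.06, within the other 40 µg/L arrays (1.04 to 1.14) and above those at 2 µg/L (0.06 to 0.41). Chance could not be excluded for the numbers of lists called. Here 11, 3, 10 and 18 divisions gave as many as the real 8, 14, 13 and 7 (highest other 13, 14, 15 and 15) at 40 and 2 µg/L against DMSO, between the doses and for DMSO against water.

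The share of probes well above background was 79.18% on 2 µg/L replicate 2 and 72.2% to 73.33% on the other 3 (gap over range 0.838), and this array lay at -4.4 on the second principal component against -23.4 to -22.4 (0.947). Among list means, DMSO replicate 4 stood apart for the target kinases (0.9) and neurons (0.834), DMSO replicate 1 for the AhR list (0.872), water replicate 2 for skeletal muscle (0.831), and 40 µg/L replicate 2 for the p53 list (0.887). At 40 µg/L replicate 1 stood apart for the AhR (0.886) and fatty acid lists (0.882), and at 2 µg/L replicate 4 for the pancreas (0.879) and thyroid lists (0.934). Among named genes, 2 µg/L replicate 4 stood apart for eevs (0.954), mep1a.1 (0.912), cela1.3 (0.917), cpb1 (0.858), ela3l (0.941) and stmn1b (0.906), and 2 µg/L replicate 1 for ifi27.1 (0.845). At 40 µg/L replicate 1 did so for asah2 (0.877), angpt2b (0.834), ugt1a1 (0.978) and elovl2 (0.922), and replicate 2 for cybb (0.878). In the controls, water replicate 3 stood apart for gch2 (0.986), arr3b (0.869) and higd1a (0.891), water replicate 4 for cela1.5 (0.875) and slc38a4 (0.866), and DMSO replicate 1 for dusp1 (0.923).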

How the results depend on the processing

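Both normexp fits, the leave-outs of 40 µg/L replicate 2 from comparisons without it and the choice among named genes were settled after seeing the data. Over the 127 gene calls named in the text, 2513 gene-and-setting results kept direction and side of the threshold, 565 kept direction only and 6 reversed. Of the 128 calls the naming rule took that are not named, 2089 kept both, 919 kept direction only and 15 reversed. For list calls 581 kept both and 134 kept direction only. The reversed ones, with no call, were crygm6 at -0.17, lipca at -0.02 and prkcz at -0.03 (40 µg/L against DMSO) and prkcz at -0.03 and slc2a1a at -0.24 (40 against 2 µg/L) under the default normexp fit. The other was prkcz at -0.04 at 40 µg/L with water as the control.

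Counts of changed probes are given in the order 40 µg/L against DMSO (1525), 2 µg/L against DMSO (486), 40 against 2 µg/L (7318) and DMSO against water (154). The default normexp fit left 0, 4, 1 and 0 by limma (7107, 6119, 13021 and 1388 at an unadjusted p under 0.05 in the main setting). It shifted the median change of all probes (0.068, 0.044, 0.035 and -0.009) by -0.265 and -0.282 at 40 µg/L against DMSO and against 2 µg/L, and by 0.114 for DMSO against water. Its 1st percentile of log2 signal was 6.98 to 10.26 on 5 arrays and 5.78 to 5.92 on the other 11, against 5.69 to 5.85 with the negative controls as background, so that fit differed between arrays. With the negative controls it gave 4134, 789, 11971 and 13 (median shift 0.167 between the doses, where no filter shifted it by 0.133). No filter gave 933, 158, 4037 and 3072, and an adjusted p under 0.01 gave 313, 91, 688 and 47. Array weights gave 14041, 8688, 19997 and 416, only the 8 arrays compared gave 451, 5953, 2128 and 11, and an ordinary test per probe gave 38, 3646, 110 and 0. Only probes above background on all arrays gave 907 at 40 µg/L against DMSO and 53 for DMSO against water, where a trended and robust prior gave 76 and quantile normalisation 73. Water as the control gave 678 at 40 µg/L (477 of the 1525 among them) and 2428 at 2 µg/L (437 of the 486), and both controls together 2507 and 3012. With only the 8 arrays compared and with an ordinary test, 2 µg/L gave more calls against DMSO than 40 µg/L did, the reverse of the main setting. Neither takes spread from the other groups. The 2 µg/L count also rose to 1941 without 40 µg/L replicate 2, which enters it only through the shared spread. Which dose has more changed probes thus depends on how the spread is estimated. Apart from this and from fewer probes or arrays entering the fit, the cause was not tested.

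With 1 array left out the counts ranged from 406 to 5621, 109 to 1941, 1469 to 13369 and 56 to 235; the arrays behind them are named beside each comparison, and 1941 is without 40 µg/L replicate 2. The list counts (8, 14, 13 and 7) ranged from 4 to 11, 11 to 15, 11 to 15 and 0 to 12. They were 4 without 40 µg/L replicate 3 against DMSO, and for DMSO against water 3, 3, 0 and 12 without DMSO replicate 1 and water replicates 2, 3 and 4. An estimated correlation gave 0 lists in all 4, fry gave 4, 3, 13 and 0, no filter gave 4 at 40 µg/L, and the default normexp 4 for DMSO against water. Single lists called by camera were lost at 40 µg/L with other scalings (immediate early 0.192 with quantile and 0.233 with negative-control normexp, inflammation 0.0918 with the latter, fatty acid 0.0616 with quantile). The same happened between the doses (immediate early 0.0603 with quantile, and 0.107 for immediate early, 0.107 for neurons and 0.0613 for xanthophores with negative-control normexp), and to the cartilage list of DMSO against water (0.0552 with quantile). No filter lost 6 list calls (adjusted p = 0.0513 to 0.222), and the mean of all probes of a gene 3 (0.0568 to 0.121).

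Calls of named genes lost with quantile normalisation numbered 12 (adjusted p = 0.0505 to 0.289). These were btg2, dusp1, crygm6 and lipca at 40 µg/L, cpa5, cry3b, cyp3a65 and lipca at 2 µg/L, and dusp2, dusp5, eno2 and stmn1b between the doses. With median centring 14 were lost (0.0503 to 0.102), namely btg2, cd36, dusp1, lipca and ptgs2b at 40 µg/L, cela1.5, cyp3a65, ela3l, lcp1, lipca and neurod1 at 2 µg/L, dusp6 and stmn1b between the doses, and urod in DMSO against water. With negative-control normexp 6 were lost (0.0602 to 0.414), namely popdc2 at 40 µg/L, lipca at 2 µg/L, and hbbe3, klhl36, prkcz and rcc1 in DMSO against water. No filter lost 25 (0.0517 to 0.105). The default normexp lost 120 with the direction kept, besides those given above as reversed. Only the 8 arrays compared lost 32, an ordinary test per probe 95 and an adjusted p under 0.01 lost 50. The ordinary test lost 41 of 41 at 40 µg/L and 0 of 29 at 2 µg/L against DMSO. It lost 47 of 50 between the doses and 7 of 7 for DMSO against water. With only the 8 arrays compared the losses were 19, 0, 8 and 5 in the same order. Water as the control lost 12 with the direction kept (0.0503 to 0.794), and also prkcz at 40 µg/L, given above as reversed (0.897). All are named beside the comparisons.

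The replicate number as a block gave 1383, 379, 7258 and 140 probes and 9, 14, 13 and 7 lists. Whether the numbers pair the arrays was not settled: deviations of same-numbered arrays correlated at 0.046 to 0.448, 0.07 to 0.165, -0.273 to 0.053 and -0.33 to 0.13. Those of differently numbered arrays correlated at -0.428 to 0.243, -0.322 to 0.34, -0.333 to 0.251 and -0.394 to 0.335. With the block, btg2 (0.0747) and lipca (0.0501) at 40 µg/L and cyp3a65 (0.0507), lipca (0.051) and otud7b (0.0707) at 2 µg/L were not called, and no other named gene lost its call. The lists called without the block were all called with it, and the AhR list at 40 µg/L against DMSO was called too (adjusted p = 0.0477, against 0.0545 without the block).

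Not run were slide and scan as a fixed or random block, since each holds 1 group, the authors' series table, which is identical to the scanner values, and normexp on mean signals, not used here. Signal over background limits the water arrays most, with 49.4% of probes well above background on replicate 1.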

Other observations

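All tests of this part were chosen after the results were seen. Calls at 40 µg/L were counted apart for probes with and without a gene symbol. Against DMSO, 806 unnamed probes rose and 170 fell (82.6% higher), and 300 and 249 of the probes with a symbol did (54.6%). The shares higher were 57.3% and 35.4% with quantile normalisation, 69.3% and 27% with median centring, and 92.4% and 71.2% with normexp from negative controls. Between the doses the shares were 61.8% (2538 and 1571) and 35.8% (1150 and 2059), and under these scalings 57.5% and 29%, 64.2% and 33.9%, and 86.7% and 58.2%. At 2 µg/L against DMSO 118 unnamed probes rose and 117 fell, next to 125 and 126 with a symbol. The difference in shares was not tested, because probes are not independent.

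Named genes of other groups also changed between the doses. Of 22 erythroid genes 3 rose and 2 fell from 2 to 40 µg/L (the same adjusted over the list alone, camera adjusted p = 0.427). The globin gene hbaa2 rose by 1.42 ± 0.25 on the log2 scale (SE, n = 4, adjusted p = 0.00692), a gene chosen here after its value was seen. The repressor arm of the clock lay 0.42 higher at 40 than at 2 µg/L (exact permutation p = 0.0286, the smallest possible, and 0.118 after adjustment over 136 tests), while the activator arm differed by -0.02, which is within the replicate spread. Of 33 heat shock genes 5 rose and 2 fell between the doses, and of 24 cholesterol synthesis genes 1 rose and 4 fell.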
